A study of Mus musculus with 2 samples.

How the data were processed

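Macrophages were grown from the marrow of C57BL/6 mice in medium with 100 ng/ml macrophage colony-stimulating factor (M-CSF) for 5 days, and total RNA was made into Illumina libraries, per the labels' protocols. M-CSF drives marrow progenitors to become macrophages. The KO library came from mice carrying LyzM-Cre, which expresses Cre recombinase from the Lyz2 locus in myeloid cells, together with floxed Tipe1 alleles. The genotype label of the KO library reads TIPE1-/- and names no Cre. The WT library has wild type as its genotype, and the series' design text describes the control mice as floxed without Cre. There was 1 library per genotype.

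The values analysed were raw read counts per gene symbol in 1 deposited table with 46095 genes and 1 column per library, per the file headers. HISAT2 and the mouse assembly GRCm38 are named in the submitters' processing notes, without a version. The counting program, the annotation, the strand setting and the read filters are not given in the sources used here. Reads of overlapping or antisense genes, and reads shared between near-identical genes, can therefore fall on the wrong member. Genes with close copies named below (Lyz1 and Lyz2, Fpr1 and Fpr2, Bcl2a1d, Rpl29, Gapdh, and the Gbp, Cd300, Clec4 and Pilr families) are uncertain for that reason. No row of the table lacked a gene name.

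Total counts were 11782664 in the WT library and 15815956 in the KO library. Effective library sizes were computed with TMM (edgeR 4.0.16, R 4.3.3), and counts were scaled to an effective size of 1e6 reads (CPM). The log2 ratio of KO over WT was taken after adding 0.5 CPM to both values, which pulls the ratio of low genes toward 0. The 12495 genes with a mean of at least 1 CPM over both libraries were tested. For each gene the ratio of CPM without the added 0.5 was given with an exact Clopper-Pearson 95% interval of the split of its reads between the libraries (scipy 1.17.1). Reads made by PCR without molecular identifiers are not independent molecules, so the intervals can be too narrow even for counting error. The intervals and detection floors cover no other source of variation. A count of 3 corresponds to 0.248 CPM in the WT library and 0.194 CPM in the KO library. With no replicates a quasi-likelihood model has no residual degrees of freedom, so no p-value was computed.

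Genes at least 2-fold apart were counted on the log2 scale, beside the same count in 100 simulated pairs of unchanged libraries with Poisson counts at these depths. For 39 gene lists (23 pathways, 13 cell types and 3 quality lists) the median log2 ratio of the tested members was set against 10000 random lists matched on mean CPM in 20 bins. A list was called higher or lower than other genes when its median lay in the upper or lower 2.5% of the random lists. That percentile describes these 2 libraries and is not a p-value. At these limits 1.85 of the 37 lists with at least 3 tested members would be called if their members behaved as independently drawn genes. Genes of 1 list can move together between cultures, so more lists could be called without an effect of the genotype. A member was counted as higher or lower when its ratio was 1.5-fold or more and its interval excluded 1. The lists share members, such as 5 genes held by both the chemokine and the NF-kB list.

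The lists, the tests, the alternatives given below and the rule for named genes were fixed before the data were examined, apart from those marked in the text as chosen later. The rule took Tnfaip8l1, its family and Lyz2, then the 12 genes with the largest ratio in each direction among those reaching 10 CPM in the higher library. Pseudogenes and predicted models were left out of those 12. It added up to 4 members per pathway list and up to 3 per cell type or quality list with a mean of at least 5 CPM, by size of log2 ratio. It also took Nos2, Arg1, Mrc1, Il1b, Tnf, Il10 and Il6 at any level, and the genes within 2 Mb of Tnfaip8l1 or Lyz2 that differed by 1.5-fold. A list of 259 mesenchymal genes, 185 of them tested, was written after the difference in stromal genes was seen. Some list members that the rule takes are not reported here. Other genes are named as examples of list members or of counts, and were chosen after their values were seen. Mitochondrial genes, which the table gives as ND1, COX1 and the like, were matched by hand. Positions and gene types came from NCBI RefSeq for GRCm38.p6, in which 41483 symbols matched directly and 1111 by a unique synonym.

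The calculation was tested on 20 simulated pairs of libraries for the comparison of KO with WT, with 200 genes changed in each and 12489 genes in the step. Of genes changed 3-fold, 95.2% were counted as at least 2-fold apart, and of genes changed 1.5-fold, 1.25%. The interval held the true ratio for 95.6% of genes. Of 200 unchanged lists of 25 randomly drawn genes, 3.5% were called, and 100% of 10 lists shifted by 1.5-fold were called in the right direction. The simulated counts varied by Poisson error only, with all other genes unchanged. In the real libraries the log2 ratios of the tested genes had a standard deviation of 0.575. These shares therefore check the calculation under its own counting model, and do not tell how it performs on cultures that differ. The alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile factors, no filter or a mean of at least 10 CPM, added values of 0.1 or 2 CPM, the mean over list members, subtraction of the median of all genes, thinning of the deeper library, and the 2-fold rule applied to the interval bound. Copies of Rpl29 were found with BLAST 2.17.0 in the GENCODE vM21 transcripts, at 95% identity or more over at least 400 bases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.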

Results

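RNA sequencing compared marrow-derived macrophages of mice with a myeloid deletion of Tipe1 with macrophages of control mice. The series title gives macrophage polarization, the range between inflammatory (M1) and tissue-repair (M2) states, as the subject. TIPE1 is encoded by Tnfaip8l1 and belongs to the TNFAIP8 family of lipid-binding proteins. Each genotype was represented by 1 library, called the WT library and the KO library here, with 11782664 and 15815956 counted reads. At least 1 read was found for 19391 genes in the WT library and 19282 in the KO library. Apoe was the most abundant gene in the WT library at 28735 CPM, and Fth1, a ferritin subunit, in the KO library at 21257 CPM. No difference below has a replicate check, and intervals in parentheses are 95% counting intervals.

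The targeted gene was checked before any other. Tnfaip8l1 (GRCm38 chromosome 17, 56162439 to 56184249, protein-coding) had 21 reads in the WT library and 3 in the KO library, 1.74 and 0.194 CPM, which is 8.94-fold lower (2.67 to 46.8). The exons removed by Cre are not given in the sources used here, so reads outside them would not register the deletion. Tnfaip8 on chromosome 18 was level, at 123.4 CPM in the WT library and 123.5 in the KO library. Tnfaip8l2, which encodes TIPE2, was 1.20-fold lower (1.10 to 1.31) in the KO library, and Tnfaip8l3 had 3 reads in each. Lyz2, the lysozyme gene whose locus carries Cre (chromosome 10, 117277541 to 117282272), was 1.86-fold lower (1.85 to 1.88) at 8028 against 14958 CPM. As the mice are described, only the KO mice carried Cre at this locus. The fall in Lyz2 therefore cannot be told apart from an effect of the Cre allele itself. Lyz1, the neighbour and close copy of Lyz2, was 2.16-fold higher, at 88.2 against 40.8 CPM.

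The KO library had more Slc13a3, a dicarboxylate transporter (222 against 4.55 CPM), and Marco, a scavenger receptor (223 against 7.62 CPM). Acod1, which makes itaconate, stood at 665 against 113 CPM, the gelatinase gene Mmp9 at 732 against 126 CPM and the formyl peptide receptor gene Fpr1 at 314 against 68.8 CPM. The receptor genes Slamf9 and Siglece were 11.2-fold and 10.9-fold higher, and the complement regulator Cd55 was 7.71-fold higher. Ehd1, Ankdd1a and D17Wsu92e (Ilrun) were 5.76-fold, 5.59-fold and 4.92-fold higher. Rpl29 had the largest ratio of the 12, at 832 against 13 reads, but shares its sequence with processed copies, of which Gm13841 had 646 against 852 reads. The 12 largest ratios in the other direction were those of Cyr61 (Ccn1), Alpl, Pmepa1, Ptprd, Thbs2, Ehd2, Tnn, Acta2, Gas1, Ctgf (Ccn2), Sdc2 and Cnn3, several of them matrix or contractile genes of fibroblasts and smooth muscle. They ran from 33.2-fold lower (16.5 to 78.0) for Cyr61 to 15.5-fold lower (8.82 to 29.8) for Cnn3. With 8 and 13 reads in the KO library these intervals overlap, so the order of these 2 genes is not resolved.

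Of 12495 tested genes, 252 were at least 2-fold higher in the KO library and 494 at least 2-fold lower, while 94.0% lay within 2-fold. Counting error alone gave means of 3.49 and 3.4 genes in the simulated pairs, with maxima of 8 and 9. At least 4-fold apart were 36 genes in the higher and 220 in the lower direction. Of 185 tested genes of a mesenchymal list, written after the difference in stromal genes was seen, 138 were at least 2-fold lower and 1 higher, and without that list 356 genes were lower. The list need not hold every stromal gene, so the 356 can still include some. Of the 220 genes at least 4-fold lower, 105 were on the list. With a mean of at least 10 CPM required, the counts were 112 higher and 92 lower, and without a filter 315 and 741. With 2 CPM added they were 156 and 313, and when the interval bound itself had to reach 2-fold 133 were higher and 347 lower.

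**Figure D1:**
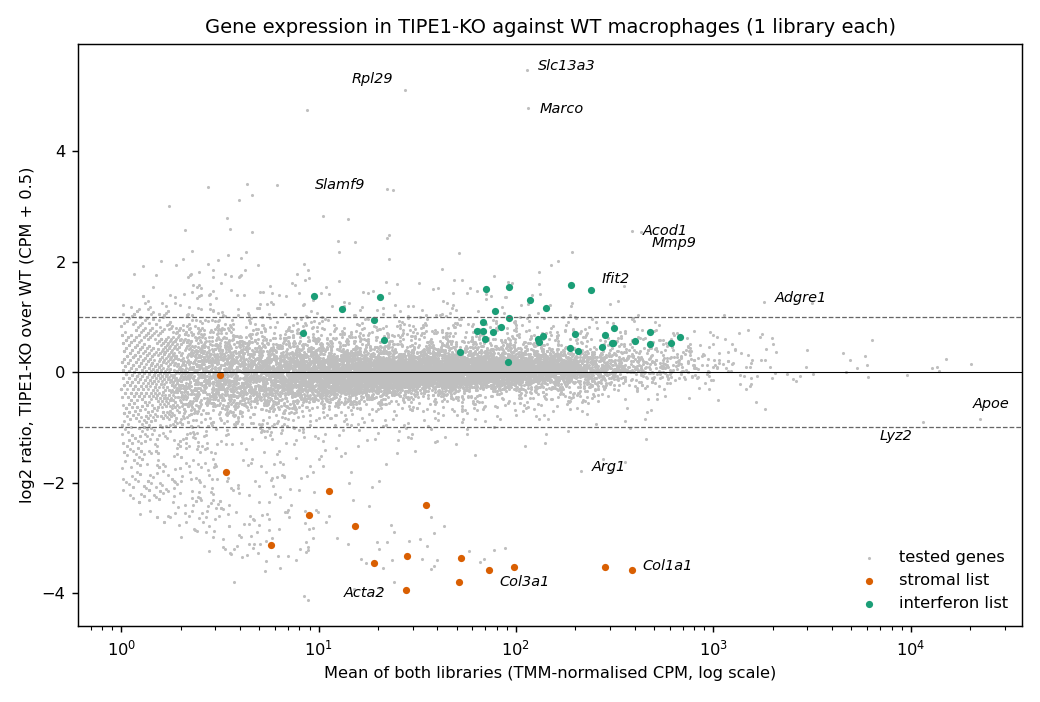
Log2 ratio of the KO over the WT library (vertical axis, after adding 0.5 CPM) against mean expression in CPM (horizontal, log scale) for the 12495 tested genes, 1 library per genotype. Dashed lines mark 2-fold; 15 of the 16 stromal genes (orange) lie far below 0 and all 38 interferon genes (green) lie above it.

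Genes associated with M1 polarization were mostly higher in the KO library, whereas those associated with M2 went both ways. Of 24 tested M1 genes 13 were higher, 3 lower and 8 neither, with a median log2 ratio of 0.85 (percentile 100), or 0.41 without a filter. The higher ones included Marco, Nfkbiz (203 against 57.5 CPM), which encodes a nuclear IkB protein that assists secondary NF-kB targets, the formyl peptide receptor gene Fpr2 (120 against 35.7 CPM) and Cxcl10 (13.9 against 5.05 CPM). Il1b was 1.77-fold higher (1.46 to 2.16) at a low level of 21.7 against 12.3 CPM. The lower M1 genes were Nos2, which encodes inducible nitric oxide synthase, at 3.37 against 6.95 CPM, Ccr7 at 1.10 against 3.89 CPM and Hif1a at 320 against 580 CPM. Il6 had 10 reads in the WT library and 5 in the KO library, and Tnf was listed at 0 in both libraries. Since the counting settings are not given, that 0 cannot be told apart from reads left uncounted, and it is not read as absence of Tnf RNA.

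Of 29 tested M2 genes 5 were higher, 5 lower and 19 neither, and the median of 0.08 was not apart from other genes (percentile 74.1), nor was the mean over members, -0.05. Arg1, the arginase gene used as an M2 marker in mice, was 3.49-fold lower (3.29 to 3.71) at 94.7 against 331 CPM. The fibronectin gene Fn1 was 3.53-fold lower. Fn1 is also on the mesenchymal list and on the monocyte list, and both stromal and monocyte genes were lower (below). Il1rn, the interleukin 1 receptor antagonist, and Folr2, a folate receptor, were 2.33-fold and 2.01-fold higher. Il10 had 59 reads in the KO library against 12, 3.85-fold higher (2.05 to 7.87). The mannose receptor gene Mrc1 stood at 415 against 389 CPM, a ratio of 1.07.

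Interferon-stimulated genes were higher together in the KO library. All 38 tested members had a log2 ratio above 0, 27 were counted as higher and 0 as lower, and the median was 0.72 (percentile 100). Rsad2, Cmpk2, Ifit2 (355 against 126 CPM) and Mx1 (104 against 36.3 CPM), which RefSeq gives as a transcribed pseudogene in this assembly, had log2 ratios from 1.49 to 1.58. Irf7, a transcription factor of the interferon loop, was 1.65-fold higher. The NF-kB list had a median of 0.57 (percentile 100), with 17 of 35 members higher, 2 lower and 16 neither. Nfkbiz and the chemokine genes Cxcl2 (84.1 against 18.5 CPM) and Ccl4 (59.8 against 20.5 CPM) were among the higher members, as were the inhibitors Nfkbia and Tnfaip3 at 1.58-fold and 1.97-fold. Csf1, which encodes M-CSF itself and is on the mesenchymal list, was 3.71-fold lower (2.93 to 4.73).

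The chemokine list was higher and the chemokine receptor list lower in the KO library. Of 16 chemokine genes 9 were higher, 2 lower and 5 neither, with a median of 0.93 (percentile 100). That median was 0.29 without a filter and the mean over members 0.42, both still called higher. Ccl3 was 2.74-fold higher at 70.3 against 25.7 CPM, while Cxcl12, a product of stromal cells, was 13.7-fold lower (7.60 to 27.3). Of 11 receptor genes 5 were lower, 1 higher and 5 neither, with a median of -0.49 (percentile 0), or -0.80 among genes with a mean of at least 10 CPM. Cxcr4 stood at 173 against 538 CPM, and Cxcr2, Cx3cr1 and Ccr2 were 2.89-fold, 2.39-fold and 2.18-fold lower. Cxcr2 is also on the neutrophil list and Cx3cr1 and Ccr2 on the monocyte list, which were lower as well. The MHC class II list had a median of -0.25, just inside the limits at percentile 2.87, with 4 of 10 members lower, 1 higher (Cd40, 2.02-fold) and 5 neither. The lower ones were Cd74, the invariant chain, at 274 against 639 CPM, the class II transactivator Ciita at 4.41 against 8.94 CPM, H2-Ab1 and H2-Eb1. The class II list was called lower without a filter, at -0.36, but not at a mean of at least 10 CPM, at -0.12 (percentile 8.19). MHC class I genes had a median of 0.12 (percentile 77.3), with Tapbp 1.58-fold higher and H2-Q4 1.38-fold lower. Without a filter their median was 0.24 and the list was called higher, while at a mean of at least 10 CPM it was 0.07 (percentile 53.2) and not called.

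Cholesterol synthesis genes had a median of 0.34 (percentile 100), with 5 of 24 higher, 0 lower and 19 neither. Hsd17b7 and the squalene epoxidase gene Sqle (61.0 against 36.9 CPM) were 1.79-fold and 1.65-fold higher. Hypoxia-related genes had a median of -0.23 (percentile 0), with 8 of 24 lower, 1 higher and 15 neither. That median was -0.13 among genes with a mean of at least 10 CPM, and the mean over members -0.46. Ddit4, an inhibitor of mTORC1, was 4.23-fold lower, P4ha2, a collagen prolyl hydroxylase subunit on the mesenchymal list, 3.29-fold lower, and Arg1 and Nos2 are also members. Glycolysis genes had a median of 0.01 (percentile 15.5), with Pfkp 1.53-fold and Hk3 1.42-fold higher, Gapdh 1.31-fold higher and Aldoc 1.48-fold lower. Oxidative phosphorylation genes had a median of 0.08 (percentile 86.2) and none of 35 was counted in either direction, the most distant being Ndufa1 at 1.37-fold. Fatty acid oxidation genes had a median of -0.10 (percentile 3.57), with Acsl1 1.75-fold higher and Cpt1a 1.45-fold lower, and were called lower without a filter at -0.16 but not at a mean of at least 10 CPM, at -0.01 (percentile 35.3). Lipid handling genes under LXR and PPAR had a median of 0.13 (percentile 85.6) over opposite members, or 0.05 without a filter and 0.20 at a mean of at least 10 CPM, not apart in either case. Lipoprotein lipase (Lpl) was 2.47-fold higher at 3676 against 1488 CPM, Nr1h3, which encodes LXR alpha, 2.06-fold higher, and Apoe 1.80-fold lower at 15920 against 28735 CPM.

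Cell cycle genes had a median of 0.28 (percentile 100), with 8 of 41 higher, 1 lower and 32 neither. Ccnd1, Kif11, Rrm2 and Top2a were 1.58-fold to 1.92-fold higher. Genes of the ATF4 and unfolded protein response had a median of 0.21 (percentile 99.9), with 4 of 30 higher, 1 lower and 25 neither. Mthfd2, the cystine transporter Slc7a11, Asns and Trib3 were 1.53-fold to 1.92-fold higher. The median was 0.14 with total counts, and the mean over the list, 0.15, was not apart from other genes. NRF2 targets had a median of 0.17 (percentile 96.3) and a mean of 0.26 that was called higher. Of 26 NRF2 members 6 were higher, among them Sod2 at 469 against 192 CPM and the peroxiredoxin gene Prdx1 at 1684 against 1027 CPM. Not apart were the lists of lysosome and phagocytosis (0.02, percentile 7.06), complement (0.02, percentile 26.6), PI3K, AKT and FOXO (0.06, percentile 65.4) and cell death (0.09, percentile 90.8). As means over members the values were 0.19 (percentile 91.3) for lysosome and phagocytosis and 0.22 (percentile 92.6) for complement, above most random lists but still not apart. Single members differed there. Gas6, a bridge to apoptotic cells that is also on the mesenchymal list, was 2.02-fold lower, Itgax 2.68-fold higher, Irs2 1.81-fold lower and Bcl2a1d 2.09-fold higher.

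**Figure D2:**
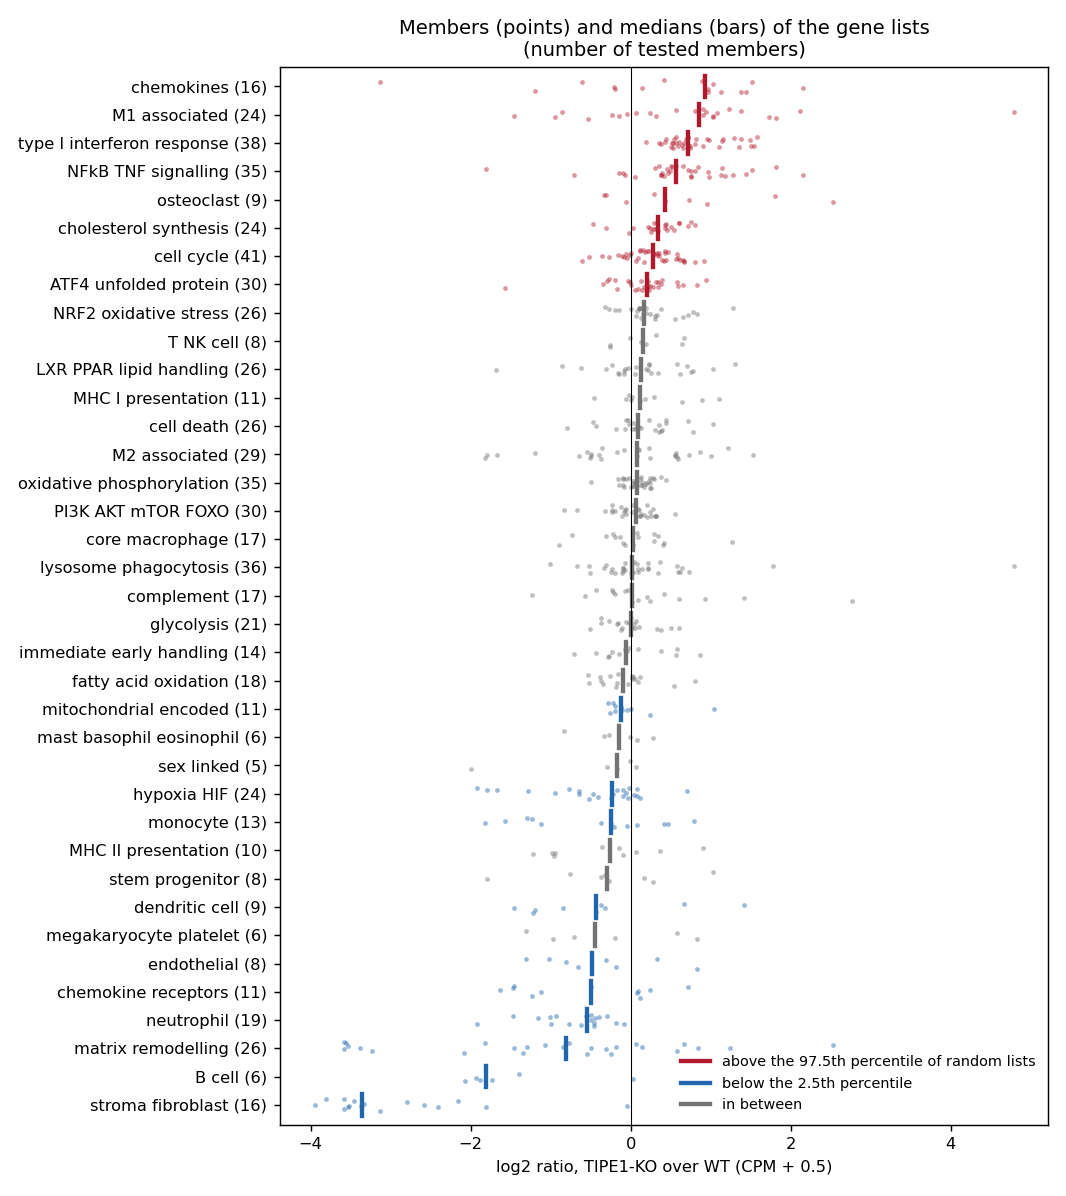
Log2 ratio of the KO over the WT library (horizontal axis, after adding 0.5 CPM) for each tested member (points) and the median (bars) of the 37 lists with at least 3 tested members, whose number stands in parentheses. Red lists lie in the upper and blue lists in the lower 2.5% of 10000 random matched lists; the medians run from 0.93 for chemokines to -3.35 for stromal genes.

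Genes of the extracellular matrix and its remodelling went in both directions. The matrix list had a median of -0.81 (percentile 0), with 14 of 26 lower, 4 higher and 8 neither, and 11 of its 26 members are on the mesenchymal list. Without mesenchymal genes the median was -0.19, still called lower. Col1a1, Col3a1 and Sparc were 11.9-fold to 12.5-fold lower. The 4 higher members were the macrophage metalloelastase gene Mmp12 (4468 against 1886 CPM), Mmp9, Plau and Plaur.

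Stromal genes gave the largest list difference among the cell type lists. Of 16 fibroblast and stromal markers 15 were lower in the KO library and Thy1 was level, with a median of -3.35, or 10.2-fold lower (percentile 0). Their summed expression was 181 CPM against 2026 CPM in the WT library. Col1a1 stood at 58.9 against 714 CPM, Col5a1 at 6.48 against 97.0 CPM and Acta2, smooth muscle actin, at 2.92 against 52.2 CPM. Core macrophage genes did not stand apart, with a median of 0.03 (percentile 11.3) over 17 members. Csf1r, the M-CSF receptor, stood at 2414 against 2646 CPM and Cd68 at 1589 against 1493 CPM. Adgre1, which encodes F4/80, stood at 2554 against 1064 CPM, a log2 ratio of 1.26.

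**Figure D3:**
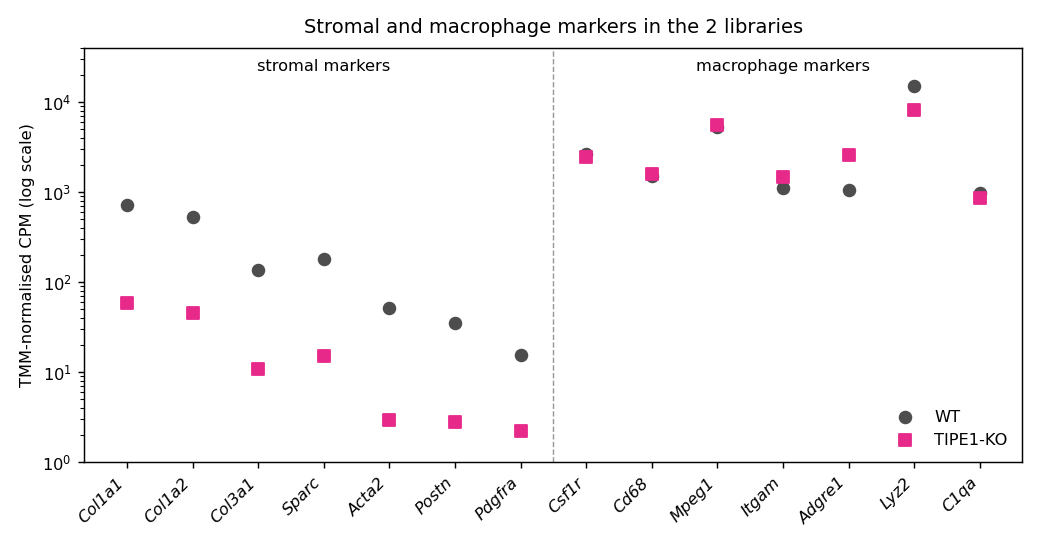
Expression in CPM (vertical axis, log scale) of stromal (left) and macrophage (right) markers in the WT library (circles) and the KO library (squares), 1 library each. The stromal markers shown lie lower in the KO library, Col1a1 at 58.9 against 714 CPM, while Csf1r and Cd68 nearly overlap.

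The monocyte, neutrophil and B cell lists were also lower in the KO library. The monocyte list had a median of -0.24 (percentile 0.03, mean over members -0.47), with 5 of 13 lower and 1 higher, 2 of the 13 being on the mesenchymal list. Its members Fn1, F13a1 and Vcan were 3.53-fold, 2.98-fold and 2.48-fold lower. The neutrophil list had a median of -0.54 (percentile 0), with 7 of 19 lower and 0 higher. The granule gene Ltf was 1.48-fold lower and Retnlg 2.11-fold lower. The B cell list had a median of -1.81 (percentile 0), or -0.90 with 2 CPM added, with 5 of 6 members lower at few reads, such as Cd79a with 40 reads in the WT library and 10 in the KO library, while Cd22 was level at 47.5 against 46.5 CPM. The dendritic list (median -0.44, percentile 0.76) had 4 of 9 members lower, including Tcf4 at 1.80-fold, and Bst2 and Itgax higher. Its median was 0.18 among genes with a mean of at least 10 CPM. The endothelial list (median -0.48, percentile 0.6) had 3 of 8 members lower and Vwf 1.80-fold higher, and its median was 0.075 at that filter and -0.30 with 2 CPM added.

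The osteoclast list was higher in the KO library, with a median of 0.43 (percentile 99.9; mean over members 0.67) and 4 of 9 members higher, 0 lower and 5 neither. The higher members were Mmp9, Acp5, which encodes the tartrate-resistant phosphatase (68.4 against 35.0 CPM), Atp6v0d2 and Dcstamp. Lists of T and NK cells (0.16, percentile 88.1), mast cells, basophils and eosinophils (-0.14, percentile 37.4), megakaryocytes (-0.45, percentile 3.96) and progenitors (-0.29, percentile 8.2) were not apart from other genes, although Cdk6 on the progenitor list was 2.05-fold higher and Itga2b on the megakaryocyte list 2.06-fold lower. The erythroid list had 1 tested member and the TIPE family list 2, too few for a percentile.

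Transcripts encoded in mitochondria had a median of -0.12 (percentile 1.89), or -0.19 with total counts, and their mean of -0.01 was not apart from other genes. Of 11 members 1 was higher, 0 lower and 10 neither. ND4L, with 32 reads in the KO library and 9 in the WT library, was the higher one, and ND2 was 1.21-fold lower. Immediate early genes, which respond to handling, had a median of -0.05 (percentile 9.4), with Egr2 1.84-fold higher and Ier3 1.65-fold lower. The sex-linked list had a median of -0.17 (percentile 4.66). Both libraries carried Y-linked transcripts, with Ddx3y at 123 CPM in the WT library and 109 CPM in the KO library, and Xist had 40 reads in the WT library and 7 in the KO library.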

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

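The settings without the mesenchymal genes, and the thinned library for the interferon list, were chosen after the results were seen, and all others were planned. No paired analysis was possible because each genotype had 1 library and no test was run. Of 841 recomputed values, 799 were labelled the same. That label means a gene count within 1.5 times, a gene ratio inside its counting interval, or a list with its call unchanged. The values themselves could still shift, as the M1 median did from 0.85 to 0.41 without a filter. Among 453 values of named genes under other scalings, 23 moved beyond their counting interval. None of the genes whose interval excluded 1 changed direction, while 3 genes whose interval included 1 crossed it, namely Tnfaip8, Cd22 and Uty under total counts and Tnfaip8 also under upper-quartile factors. The median of all genes was 0.01 with TMM, 0.02 with DESeq2 factors, -0.00 with upper-quartile factors and -0.06 with total counts. Of the 18 called lists, 14 kept their call under each alternative run for them, which left out a mean of 10 CPM or more for the B cell list, with too few members there, and removal of the mesenchymal genes for the stromal list. Counts of genes at least 2-fold apart followed the filter and the added value. They were 112 higher and 92 lower at a mean of 10 CPM or more, where fewer genes are tested, 156 and 313 with 2 CPM added, and 133 and 347 at the interval bound. The counts rose to 315 higher and 741 lower without a filter, where more genes are tested, and to 309 and 588 with 0.1 CPM added. Without a filter the class II list (-0.36), the class I list (0.24) and fatty acid oxidation (-0.16) became called, whereas at a mean of 10 CPM or more they were -0.12, 0.07 and -0.01 and not called. Also without a filter the dendritic list (-0.22) and the mitochondrial list lost their call. The class II list was also called with 0.1 CPM added (-0.28) and without the mesenchymal genes (-0.25). At a mean of 10 CPM or more the dendritic (0.18) and endothelial (0.075) medians reversed and were not called. Lists that were not apart under any setting but moved by over 1.5 times included T and NK cells (-0.00), mast cells, basophils and eosinophils (-0.25) and megakaryocytes (-0.22) without a filter, and the sex-linked list (-0.48) and cell death (0.15) as means. With the mean over members the call was lost for ATF4 (0.15), dendritic (-0.42), endothelial (-0.39) and mitochondrial (-0.01) genes and gained for NRF2 targets (0.26). The cause of these shifts was not tested. Depth limits genes near 1 CPM, Tnfaip8l1 among them, whose ratio rests on 21 and 3 reads.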

Other observations

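The gene families, the abundant genes and the tests of the stromal, interferon and Rpl29 patterns were chosen after the results were seen, whereas the windows around Tnfaip8l1 and Lyz2 were planned. Families of myeloid surface receptors, picked for their values and not tested for enrichment, held members that were higher in the KO library, as were 6.47% of all tested genes by the same 1.5-fold rule, with 7.23% lower. Of 4 tested Slamf genes 3 were higher, with Slamf8 2.89-fold higher and Slamf7 at 550 against 324 CPM. Both formyl peptide receptor genes and all 3 tested Pilr genes were higher, with Pilra 3.22-fold up at 81.7 against 25.4 CPM. Of 5 tested Siglec genes 1 was higher and 0 lower, with a median log2 ratio of 0.03. Of 8 tested Cd300 genes 4 were higher and 1 lower, where Cd300e had 115 reads against 5 and Cd300ld3 126 against 12, whereas Cd300a was 1.64-fold lower. Of 7 tested Clec4 and Clec5 genes 3 were higher and 1 lower. Clec4e, which encodes the lectin Mincle, was 3.45-fold higher (3.26 to 3.65), while Clec4n, which encodes Dectin-2, was 1.82-fold lower. Of 14 interferon-inducible GTPase genes of the Irg and Gbp families 8 were higher and 0 lower, and of 8 tested Ifi200 genes 6 were higher. Pydc3 of that family was lower, with 84 reads in the WT library and 4 in the KO library.

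Among genes with a mean of at least 100 CPM, 34 were at least 2-fold higher in the KO library and 12 lower, 8 of the latter outside the mesenchymal list. The higher ones included the integrin gene Itgal (263 against 64.8 CPM) and Alas1, the rate-limiting enzyme of haem synthesis (240 against 62.3 CPM). The 8 lower ones were Arg1, Cxcr4, the coagulation factor gene F13a1 (139 against 413 CPM), Arl4c, Kif3a, Cd74, S1pr1, which encodes a sphingosine phosphate receptor (89.5 against 195 CPM), and Tgfbi (118 against 249 CPM). Ribosomal protein genes were level, with a median log2 ratio of 0.01 over 83 genes and 1 gene higher (Rpl29) and 1 lower (Rpl13, 1.65-fold).

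Stromal genes were lower together in the KO library, Col1a1 at 58.9 against 714 CPM. A candidate explanation is a larger share of marrow stromal cells in the WT culture. Of 122 mesenchymal genes outside the stromal list and the lowest genes already seen, 76 (62.3%) were at least 2-fold lower. The share among all tested genes was 3.95%. Mesenchymal genes on other lists reported above were not left out, and the mesenchymal list was written after the stromal difference was seen. The count is therefore no independent check. Of the 185 tested mesenchymal genes, 50 still reached 10 CPM in the KO library. Lineage genes such as Prrx1 (39.7 CPM in the WT library, 2.92 in the KO library) and Cdh11 were lower too, with a median of -2.53 and 7 of 10 at least 2-fold lower. They were listed after the stromal difference was seen, and genes already inspected were not left out. They therefore give no independent check on a change limited to matrix and TGF-beta target genes. Whether the genotype or the dissection and culture of 1 marrow set the stromal level stays open, and no sort is named in the labels.

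Interferon genes were higher in the KO library. Dilution of WT macrophage RNA by stromal RNA would raise core macrophage genes equally, but the interferon median exceeded the core macrophage median by 0.68. The median was 0.73 after thinning the deeper library. Thinning leaves ratios scaled to library size unchanged on average, so it could not decide whether sequencing depth played a part. A culture or animal difference unrelated to the genotype cannot be told apart from an effect of the deletion, since there was 1 library per genotype. The hypothesis that loss of TIPE1 raises interferon genes therefore remains untested.

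Rpl29 had 832 reads in the KO library and 13 in the WT library. Summed over Rpl29 and its near-identical processed copies, 10 genes with reads, the ratio was 1.58 (1.46 to 1.71), at 123 against 78.1 CPM. Reads shared between Rpl29 and the copies are a candidate explanation. The sum cannot show why the split of reads among them differed between the libraries. The copy Gm13841 had 852 reads in the WT library and 646 in the KO library, and Gm8210 had 62 and 41. In the other direction, Gm6344 had 2 and 268, Gm10709 had 1 and 84, and Gm5561 had 3 and 22. Which copy was transcribed in which library, and whether the genotypes differ in sequence there, was not tested.

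Within 2 Mb of Tnfaip8l1, 8 of 48 tested genes were 1.5-fold or more apart, 16.7% against 16.5% of all tested genes (percentile 56.6 of windows with as many genes). They were Adgre4, Zfp119a, Ebi3, C3 and Adgre1, which were higher in the KO library, and Vmac, Slc25a23 and Tnfsf14, which were lower. Ebi3, a subunit of interleukin 27, was 2.33-fold higher at 67.4 against 28.9 CPM, and C3 was 1.52-fold higher at 533 against 349 CPM. Around Lyz2, 4 of 22 genes were 1.5-fold or more apart (percentile 62.1), namely Lyz1, Gm8960, Gm9030 and Gm33481. The count takes the ratio alone, and the intervals of Gm9030 (11 reads in the WT library, 28 in the KO library) and Gm33481 (18 and 15 reads) include 1.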
